A study of Mus musculus with 6 samples.

How the data were processed

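RNA of the medial ganglionic eminence (MGE), the ventral forebrain region that generates many cortical interneurons, was sequenced from mouse embryos at embryonic day 12.5. The 6 libraries came from 3 wild type and 3 Sp9 null samples of mixed CD1, 129S6 and C57BL/6J descent, per the labels. The labels' protocols state dissection in cold buffer, freezing, extraction of total RNA and standard Illumina library preparation, with wild type littermates as controls. They give neither the strandedness of the libraries nor whether each sample came from a separate embryo or litter, so p-values measure the spread between these samples, which may be partly technical.

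The deposited table gives, per the file headers, a read count per gene and library and an FPKM value (fragments per kilobase, scaled by the library total) for the same genes. The submitters' processing notes name TopHat, Cufflinks 2.1.1 and the genome build GRCm38.p4, without stating which step each served. The program that made the whole-number counts is not given in the sources used here. The deposited FPKM values equalled the count divided by 1 fixed length per gene and by the library's count total, within a relative tolerance of 0.001, for 21180 of the 21180 genes counted in 2 or more libraries. They therefore hold the same measurements as the counts. Coordinates are those of the deposited table, on GRCm38. Of 34267 identifiers also present in GENCODE M21, 80.8% had the same start and end there. The table lists 34745 genes by unique identifier, and 59 symbols belong to more than 1 identifier. No values were summed. The number of unused sample columns was 0.

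Library totals were 9536050, 10914147 and 9917457 counts for wild type replicates 1, 2 and 3, and 6826447, 10979280 and 9430442 for Sp9 null replicates 1, 2 and 3. A floor of 3 counts per library corresponded to between 0.273 and 0.440 CPM (counts per 1000000 counts of the library), and covers counting error only. In each genotype the pairs of replicates differed by more than counting noise, with chi-square values per degree of freedom from 3.28 to 21.94 over genes with 20 or more summed counts, so no library was treated as a repeat of another.

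Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default expression filter and robust dispersion estimates. Genotype was the only term. The 14929 genes that passed the filter were tested, the test was two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Fold changes are log2 values of Sp9 null over wild type. Their standard errors are approximate, obtained as the size of the log2 fold change over the square root of the F statistic. For genes with 0 counts in all null libraries, least folds were computed against 3 counts summed over the null group. The Sp9 level was also compared by a two-sided exact permutation test, whose smallest possible p with 3 against 3 libraries is 0.1.

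Both genotypes carry replicate numbers 1 to 3. Deviations from the genotype mean correlated across genes by 0.336, 0.729 and 0.535 between the libraries with the same number 1, 2 and 3. By the criterion of a correlation over 0.1 in all 3 pairs, the numbers were taken to pair the samples. Numbers 1 and 3 were not told apart by it, since wild type 1 correlated by 0.354 with null 3 and wild type 3 by 0.23 with null 1, while unlike pairs with a number 2 lay between -0.617 and -0.387. Deviations from a genotype mean cancel over its libraries, so the 3 correlations are not independent of each other. A fit with numbers 1 and 3 swapped in 1 genotype was not run. The pairing comes from the data, because the labels do not state what a number marks, and the blocked calls rest on it. A fit with the replicate number as a block was therefore given beside the unblocked one. Its biological coefficient of variation was 0.068, against 0.171 without the block. Each fit was tried on its own simulated counts, drawn from the real means and library sizes for 14929 genes, of which 200 were changed. The unblocked fit recovered 20.9%, 56.7% and 87.9% of genes changed 1.5-, 2- and 4-fold, and 6.8% of its calls were false. For the fit with the block, the counts were drawn with a mean per replicate number and the lower dispersions of that fit. It recovered 62.7%, 91.0% and 98.5%, and 11.1% of its calls were false, above the nominal level. The pairing was thus built into those counts, and the percentages do not compare the fits on the same data.

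Before the data were examined, 25 gene lists were fixed, 14 of topics and 11 of markers of other cell types, regions or sex. They were tested with camera in edgeR and limma 3.58.1 at a preset correlation of 0.01, with Sp9 left out, and adjusted over the 24 lists with 3 or more measured genes. The choroid plexus list had 1 measured gene and was not tested. Camera was repeated with an estimated correlation, and the directional fry test was run. In simulated data camera found a planted list and gave an unadjusted p under 0.05 for 0 of 50 random lists. The simulated genes varied independently of each other, so this check cannot show whether the preset correlation suits lists of co-regulated genes.

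Genes are named by a rule also fixed before the data were examined. Sp9 comes first, then up to 12 rises and 12 falls, ranked by fold change, among called genes whose null values all lay on the same side of all wild type values and whose median was at least 1 CPM, leaving out systematic names. From each list, up to 4 called members per direction and up to 2 not called may be named. The same rule was applied to the fit with the block. The values of 3 list members that it would allow are not reported here, though list counts and tests include them. Rprm, Nkx2-1, Zeb2, Dlx5, Sst, Cxcr4, Erbb4 and Foxp1, and the genes of the closing observations, fall outside the rule and were chosen after their values were seen.

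The alternatives fixed beforehand were the block, limma on log2(FPKM + 0.5), with pseudocounts of 0.1 and 1, quantile normalization or no trend, over genes with a mean FPKM of at least 0.5; no count filter and a mean of at least 2 CPM; median-of-ratios and upper quartile scaling; DESeq2 1.42.0; a fold of at least 1.5; an adjusted p under 0.1; and each library left out in turn. Others, added after seeing the data, combined the block with DESeq2, limma-voom, no filter or a left-out pair, or left out replicate 2 of both genotypes, genes within 20 Mb of Sp9, a gene cluster near Sp9, or genes at 0 in all null libraries. The further stomach and pancreas, microglial and immune lists of the closing observations were changed after counts were seen, and their tests were therefore run on all names as first looked up, without genes whose values had been shown; the interferon list keeps such genes.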

Results

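The comparison asks which transcripts of the E12.5 MGE differ when Sp9, a zinc finger transcription factor of the developing ventral forebrain, is lost. Expression was measured by RNA-seq in 3 wild type and 3 Sp9 null libraries, with 6826447 to 10979280 counts each. Mitochondrial genes took 2.20% to 2.28% of the counts in the wild type libraries, and 2.32%, 3.43% and 3.41% in null replicates 1, 2 and 3. The first principal component, with 51.8% of the variance, set replicate 2 of both genotypes apart from the other libraries, and the second, with 23.1%, separated the genotypes. Replicate 2 also held few transcripts of Tbr1, a gene of cortical excitatory neurons, and of Otp, a hypothalamic gene. Tbr1 had 7 counts in wild type and 1 in null replicate 2, against 141 to 395 in the other libraries, and Otp had 0 and 1 against 19 to 34. Xist, expressed from the inactive X chromosome of females, was at 2681, 2400 and 651 CPM in wild type replicates 1, 2 and 3 and at 1406, 1012 and 2.02 CPM in the null replicates. Ddx3y, of the Y chromosome, was at 1.78, 22.2 and 52.2 CPM in the wild type and 37.5, 51.6 and 55.7 CPM in the null replicates. Xist and Y transcripts thus occurred together in 5 of the libraries. Those libraries appear to hold RNA of both sexes, and so of more than 1 embryo, unless transcripts crossed between samples, which was not tested.

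Sp9 itself (ENSMUSG00000068859, chromosome 2, 73271925 to 73284706) fell 17.5-fold in the null libraries. It had 1939, 2700 and 1870 counts in wild type replicates 1, 2 and 3 and 89, 116 and 118 counts in the null replicates. The mean was 212 ± 31.0 CPM in wild type and 12.1 ± 1.13 CPM in null libraries (SD, n = 3 each). The log2 fold change was -4.13 (SE 0.14, edgeR adjusted p = 2.54e-05). The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. The labels and the Sp9 level thus matched in all 6 libraries.

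Without the replicate block, 22 of 14929 genes were called, 7 higher and 15 lower in the null libraries (edgeR quasi-likelihood test). With the block 597 genes were called, 332 higher and 265 lower, including all 22. Most of the added changes were small, since 432 of the 597 were under 1.5-fold and the median absolute log2 fold change was 0.38. In 392 of the 597 the null values lay outside the wild type range, which was so for 12.6% of all tested genes, where chance gives 10%. Direction held for 593 of the 597 with each pair left out in turn, but only 83 were called with each pair left out and by DESeq2 with the block, 43 higher and 40 lower. These 83 include Sp9, 18 genes within 20 Mb of it and 18 with 0 counts in all null libraries. Within 20 Mb, 9.63% of tested genes were among the 83, against 0.43% elsewhere. The blocked count was 1193, 126 and 219 without pair 1, 2 and 3. The unblocked count was 2, 11 and 6 without wild type replicate 1, 2 and 3, and 34 without null replicate 2.

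Among the 22 genes, 12 had 0 counts in all null libraries, and 11 of these are known as stomach or exocrine pancreas genes. They were Pgc and Gkn1, Gkn2, Tff1, Muc5ac and Chia1, which encode secreted stomach products, and Clps, Amy2a5, Amy2a4, Pla2g1b and Ctrb1, which encode pancreatic digestive enzymes or their cofactor. Pgc was at 44.5 ± 7.85 CPM in wild type (SD, n = 3) and at least 399.6-fold lower in the null libraries. Clps was at 13.9 ± 2.47 CPM and at least 124-fold lower, and Gkn1 at 10.4 ± 2.32 CPM and at least 92.8-fold lower. Ctrb1 had the smallest bound of the 11, at least 32.6-fold lower. Amy2a4 and Amy2a5 are near-identical copies, so their counts cannot be assigned securely to either. The 11 genes together took 102.56, 101.15 and 130.58 CPM in wild type replicates 1, 2 and 3 and 0 in the null libraries. The 12th gene, the predicted Gm15318, overlaps Tff1. Without the block, of the 11 only Pgc kept its call without wild type replicate 1, Pgc, Clps and Gkn1 without wild type replicate 3, and all but Muc5ac, Amy2a4, Gkn2, Pla2g1b and Ctrb1 without wild type replicate 2; Pla2g1b and Ctrb1 also lost theirs without null replicate 1. With the block, all 11 kept their calls with each pair left out in turn. Without genes at 0 in all null libraries the unblocked count was 10.

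The other called genes were counted in both genotypes. St18, a zinc finger transcription factor of pallidal neurons, fell from 132 ± 12.2 to 49.2 ± 9.59 CPM (SD, n = 3), a log2 fold change of -1.43 (SE 0.15, edgeR adjusted p = 0.0111). Kcnq3, a voltage-gated potassium channel subunit on chromosome 15 (65986387 to 66286224), rose by 1.12 (SE 0.09, adjusted p = 0.00336), from 50.6 ± 1.55 to 110 ± 8.57 CPM. Rasgef1b, an exchange factor for small GTPases, rose by 1.001 (SE 0.12, adjusted p = 0.0192). Idi2, an isopentenyl diphosphate isomerase gene, had 4 counts over the wild type and 59 over the null libraries, a depth-scaled ratio of 16.4 (95% exact counting interval 6.09 to 62.3). Metap1d, a mitochondrial methionine aminopeptidase gene, rose by 1.40 (SE 0.10, adjusted p = 0.00319), from 38.8 ± 4.19 to 103 ± 4.11 CPM. Dlx1, a homeobox gene of ventral forebrain neurons, rose by 0.69 (SE 0.09, adjusted p = 0.0340), from 918 ± 64.6 to 1483 ± 74.6 CPM. Rprm, a gene of cell cycle arrest, fell, with a log2 fold change of -0.82 (SE 0.11, adjusted p = 0.0340). The predicted genes Gm21897 and Gm26686 made up the rest of the 22. St18, Rasgef1b, Idi2, Dlx1 and Rprm each lost their call when wild type replicate 1, 2 or 3 or null replicate 1 was left out, and all of these but St18 also without null replicate 3. Kcnq3 and Metap1d lost theirs without wild type replicate 1. By limma on FPKM, Rprm, Idi2 and Dlx1 missed the threshold in some settings, with adjusted p from 0.0511 to 0.111. With the block, all of these but St18 kept their calls with each pair left out in turn, and St18 had adjusted p = 0.202 without pair 1.

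**Figure D1:**
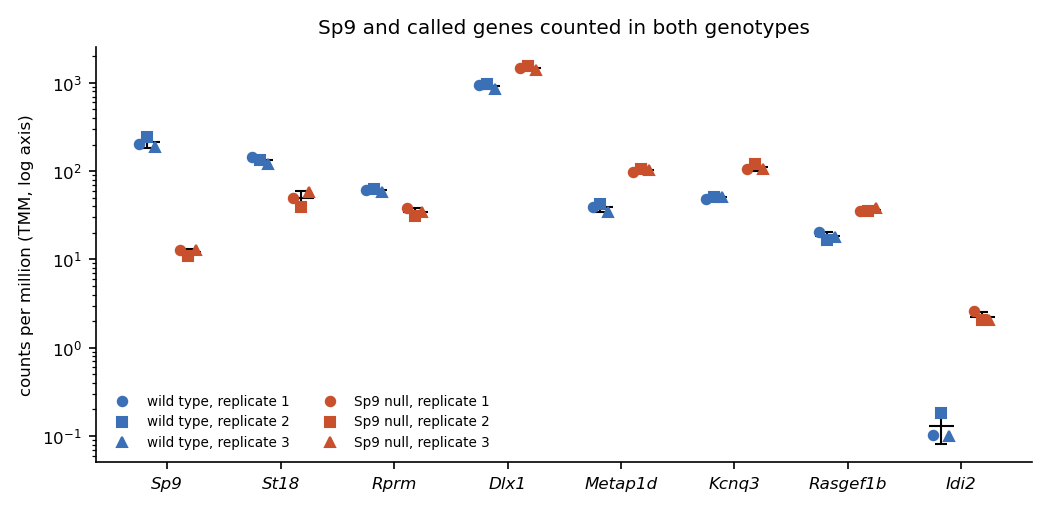
CPM on a log axis for Sp9 and 7 called genes in each library; markers give the replicate number, horizontal bars the mean and error bars the SD of 3 libraries. The null libraries lie wholly below the wild type libraries for Sp9, St18 and Rprm and wholly above them for the other 5 genes.

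Metap1d, Dlx1 and Rprm lie on chromosome 2 at 1.79, 1.75 and 19.19 Mb from Sp9. With the block, 36 of 187 tested genes within 20 Mb of Sp9 were called (19.25%), against 560 of 14741 elsewhere (3.80%), an odds ratio of 6.04 (95% interval 4.03 to 8.83, Fisher's exact test p = 2.48e-15). They included Pdk1, a pyruvate dehydrogenase kinase gene at 1.39 Mb, with a log2 fold change of 1.60 (SE 0.19), Itga4, an integrin gene at 6.02 Mb, with 1.02 (SE 0.16), and Ube2l6 at 11.53 Mb, with 1.20 (SE 0.24). The edgeR adjusted p with the block was 2.00e-07, 5.58e-05 and 0.00134. Ube2l6 lost its call without pair 2 and by DESeq2. Of the 36 genes, 4 are predicted genes clustered at a shared site; without the 6 tested genes of that cluster 32 of 181 were called, an odds ratio of 5.44. The antisense gene Dlx1as overlaps both Metap1d and Dlx1, and since strand is not stated, reads of the 3 genes may not be fully separated.

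**Figure D2:**
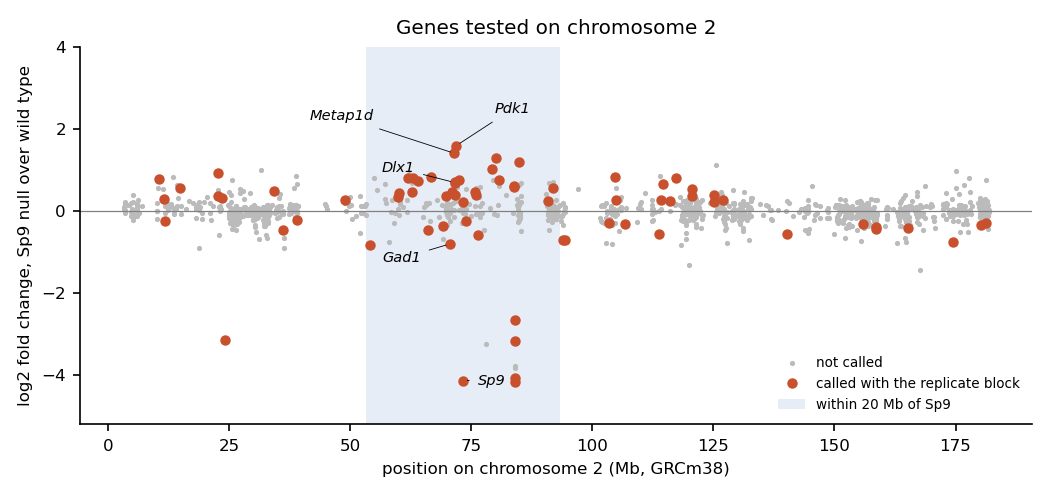
Log2 fold change of Sp9 null over wild type with the replicate block against the position of each tested gene on chromosome 2 (Mb, GRCm38). Filled red points are called genes, and 36 of the 187 tested genes in the shaded 20 Mb on either side of Sp9 are called.

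Of 12 measured MGE transcription factors, 0 were called without the block, and 1 rose and 4 fell with it (adjusted over the list alone, 1 and 4 without, 4 and 5 with the block). Lhx6, which directs MGE interneuron differentiation, fell from 519 ± 51.3 to 378 ± 33.2 CPM, with a log2 fold change of -0.45 (SE 0.06, blocked edgeR adjusted p = 6.01e-06). Maf and Nkx6-2 fell by 0.82 and 0.68 on the log2 scale, and Cux2, a homeobox gene, rose by 0.43. The regional determinant Nkx2-1, at 0.15 (SE 0.06), and Zeb2, at 0.11 (SE 0.06), did not pass. Lhx6 lies on chromosome 2 (36081953 to 36105408), as does Sp9. It kept its blocked call with each pair left out in turn and by DESeq2. Maf, Nkx6-2 and Cux2 lost theirs without pair 2, and Nkx6-2 also without pair 3 and by DESeq2. The list as a whole did not pass (camera adjusted p = 0.337, and 0.288 with the block); its median was 0.01 and its mean -0.12.

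Among 10 pan-subpallial transcription factors, Dlx1 rose without the block, and with it 3 rose, namely Dlx1, Dlx2 and Dlx6os1, and 1 fell (adjusted over the list alone, 3 rose and 1 fell without, 4 and 1 with the block). Dlx2, at 1.73 Mb from Sp9, rose by 0.39 (SE 0.06, blocked edgeR adjusted p = 3.91e-05) and kept its call with each pair left out in turn. Dlx6os1, which overlaps Dlx6, rose by 0.24 and lost its call without pair 2 and without pair 3. Dlx5, at 0.07 (SE 0.08), did not pass. The list was higher by camera, with adjusted p = 0.0249 and 0.00696 with the block. Without the block it did not pass without wild type replicate 3 (0.0882) or null replicate 2 (0.0546). With an estimated correlation the adjusted p was 0.522, and 0.829 with the block.

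Of 5 measured genes of GABA synthesis and transport, 0 were called without the block, and with it 3 fell and 1 rose (adjusted over the list alone, 1 fell without, 4 fell and 1 rose with the block). Gad1, which makes most GABA in neurons and lies 2.70 Mb from Sp9, fell from 236 ± 24.1 to 137 ± 30.8 CPM, with a log2 fold change of -0.80 (SE 0.07, blocked edgeR adjusted p = 3.15e-10). Its paralogue Gad2, also on chromosome 2, rose by 0.37 (SE 0.06, adjusted p = 5.58e-05). The vesicular GABA transporter Slc32a1 fell by 0.40. Gad1 and Gad2 kept their blocked calls with each pair left out in turn, and Slc32a1 lost its call without pair 2 and by DESeq2 with the block. The list was lower by camera, with adjusted p = 0.0345 and 6.75e-05 with the block. Without the block it did not pass without wild type replicate 1 (0.0988) or 3 (0.0908) or null replicate 2 (0.224). With an estimated correlation the adjusted p was 0.781, and 0.829 with the block.

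The list of pallidal and cholinergic projection neurons, with 12 measured genes, was lower without the block (camera adjusted p = 0.0339) and did not pass with it (0.164); with an estimated correlation the adjusted p was 0.781 and 0.829. Without the block it also did not pass without wild type replicate 1 (0.139) or 3 (0.0908) or null replicate 2 (0.377). St18 was its only member to pass without the block. With the block St18 fell and Gbx1, a homeobox gene, rose by 0.53 (SE 0.09, blocked edgeR adjusted p = 0.000145), a call lost without pair 3; adjusted over the list alone the counts were the same. Of 11 measured cortical interneuron subtype genes, 0 passed without the block, and with it Calb1, encoding a calcium-binding protein, fell from 24.7 ± 4.20 to 9.76 ± 5.25 CPM and Kcnc2, a potassium channel gene, rose by 0.67 (adjusted over the list alone, 0 without, and 1 up and 2 down with the block). The blocked log2 fold change of Calb1 was -1.42 (SE 0.24, adjusted p = 0.0161), and adjusted p = 0.0515 without pair 1. Kcnc2 lost its call without pair 2, without pair 3 and by DESeq2 with the block. Sst, encoding somatostatin, was at 13.1 ± 6.58 CPM in wild type and 12.6 ± 6.91 CPM in null libraries (blocked log2 fold change -0.06, SE 0.15) and did not pass. That list did not pass by camera (adjusted p = 0.997, and 0.999 with the block), and its mean, -0.02, differed in sign from its median, 0.155 (0.110 with the block).

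Of 24 interneuron migration genes, 0 were called without the block, and with it 6 rose and 2 fell (adjusted over the list alone, 0 without, 8 and 3 with). The guidance receptor genes Epha3, Robo1, Plxna4 and Dcc rose by 0.34, 0.28, 0.32 and 0.29, and Ackr3, a chemokine receptor gene, and Epha4 fell by 0.39 and 0.25. Cxcr4 and Erbb4, receptor genes of migrating interneurons, had blocked log2 fold changes of -0.05 (SE 0.17) and -0.01 (SE 0.07) and did not pass. All of these calls but that of Ackr3 were lost without pair 2. Those of Robo1, Plxna4, Dcc, Epha4 and Ackr3 were lost without pair 3. By DESeq2 with the block, all but that of Epha4 were lost. The list did not pass by camera (adjusted p = 0.343, and 0.0782 with the block).

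**Figure D3:**
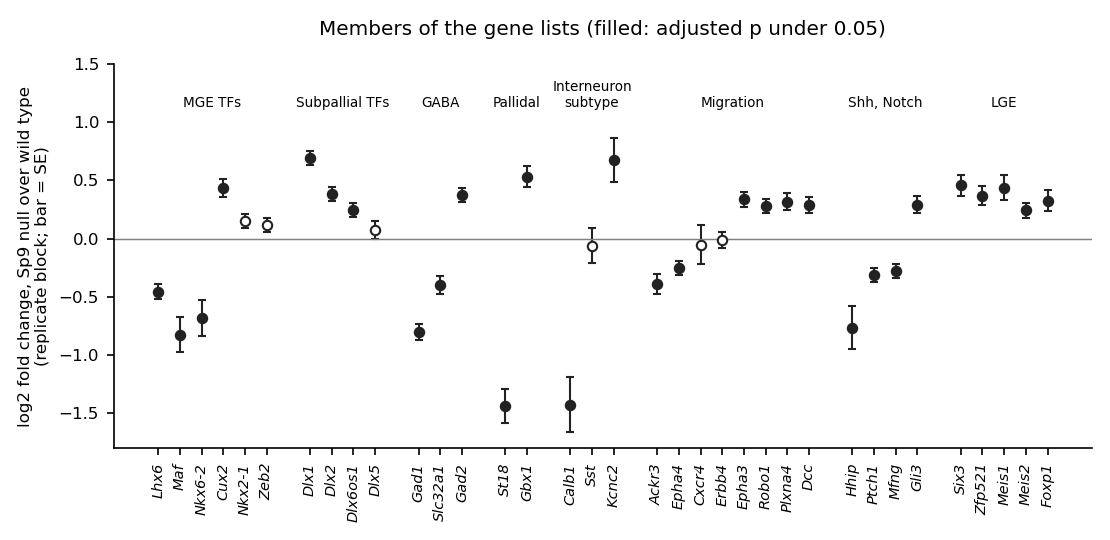
Log2 fold change of Sp9 null over wild type with the replicate block for named members of the fixed gene lists; bars give the approximate SE, and filled points have an adjusted p under 0.05. Gad1 lies at -0.80 and Gad2 at 0.37 within the same list.

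Among 11 genes of the Shh pathway, 0 were called without the block; with it Ptch1, the Shh receptor gene, and Hhip, a hedgehog-binding protein gene, fell by 0.32 and 0.77, and the transcription factor gene Gli3 rose by 0.29 (adjusted over the list alone, 1 fell without, 1 rose and 3 fell with the block). All 3 calls were lost without pair 2. That of Gli3 was also lost without pair 3, and those of Gli3 and Hhip by DESeq2 with the block. Of 13 Notch pathway genes, Mfng, a glycosyltransferase gene, fell by 0.28 with the block (adjusted over the list alone, 2 fell). Mfng lost its call without pair 2, without pair 3 and by DESeq2 with the block. The camera adjusted p was 0.102 and 0.0971 for Shh and 0.477 and 0.164 for Notch, without and with the block. Of 14 pan-neuronal genes Tubb3 and Stmn3 fell by 0.40 and 0.29 and Elavl4 rose by 0.32 with the block (adjusted over the list alone, 2 rose and 2 fell). These calls were lost without pair 2, and those of Stmn3 and Elavl4 also without pair 3 and by DESeq2 with the block. The list did not pass (camera adjusted p = 0.997 and 0.633). With the block its median was 0.03 and its mean -0.02.

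No member was called in either edgeR fit among 20 cell cycle, 12 p53 and apoptosis, 5 other Sp family, 7 immediate early and stress or 13 radial glia genes, where 0, 1, 0, 0 and 0 had an unadjusted p under 0.05 without the block and 5, 1, 1, 0 and 1 with it. Adjusted over the list alone, 0 passed in these lists. Their camera adjusted p without and with the block was 0.705 and 0.372, 0.744 and 0.744, 0.509 and 0.407, 0.744 and 0.633, and 0.997 and 0.923. The radial glia median and mean differed in sign, at -0.03 and 0.006 (-0.03 and 0.002 with the block).

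Of the marker lists, the microglia list stood out. Of 9 measured genes 0 passed singly without the block (7 fell adjusted over the list alone), and 6 fell with it (8 over the list alone). The purinergic receptor gene P2ry12 fell from 5.59 ± 1.06 to 0.63 ± 0.43 CPM, with a blocked log2 fold change of -3.11 (SE 0.35, edgeR adjusted p = 9.82e-08). The receptor genes Cx3cr1 and Csf1r fell by 2.11 and 1.11. Aif1 fell by 2.36. P2ry12, Cx3cr1 and Csf1r kept their blocked calls with each pair left out in turn. Aif1 lost its call without pair 2, without pair 3 and by DESeq2 with the block. The list was lower by camera, with adjusted p = 2.69e-20 and 8.80e-14 with the block. With an estimated correlation the adjusted p was 0.136, and 0.829 with the block.

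Of 16 measured markers of the lateral ganglionic eminence (LGE) and striatum, 0 were called without the block, and 5 rose and 0 fell with it (adjusted over the list alone, 0 without, 7 and 1 with). The transcription factor genes Six3, Meis1, Zfp521, Foxp1 and Meis2 rose by 0.46, 0.44, 0.37, 0.33 and 0.24. All 5 lost their calls without pair 2, without pair 3 and by DESeq2 with the block. The list passed only with the block (camera adjusted p = 0.0351, against 0.102; 0.829 with an estimated correlation). The pallial glutamatergic list, with 5 measured genes, also passed only with the block (adjusted p = 0.0351, against 0.365; 0.829 with an estimated correlation). Its member Tbr1, which lies 11.47 Mb from Sp9, rose by 0.81 (SE 0.19, blocked edgeR adjusted p = 0.0238), higher in 2 of 3 pairs. Tbr1 lost its call without pair 3 and by DESeq2 with the block. Adjusted over the list alone, 2 of the 5 rose with the block.

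Among the remaining markers with the block, Pdgfra, of oligodendrocyte progenitors, fell by 0.45, and the embryonic globin genes Hba-x and Hbb-bh1 rose by 0.41 and 0.33; without the block none was called. Of these 3, Hba-x alone kept its blocked call without each of the pairs. Adjusted over the list alone, with the block, 1 oligodendrocyte progenitor gene fell, 3 erythroid genes rose and 1 fell, 1 caudal gene fell, and 1 diencephalic and 1 choroid plexus gene rose. No member was called in either fit among 4 caudal ganglionic eminence, 5 preoptic, hypothalamic and diencephalic, 11 endothelial, 8 mural and meningeal, 1 choroid plexus and 6 sex-linked genes. Of these, 0 had an unadjusted p under 0.05 without the block, and 1, 1, 0, 0, 1 and 1 with it. The camera adjusted p, without and with the block, was 0.744 and 0.923 for caudal, 0.365 and 0.139 for diencephalic, 0.997 and 0.999 for endothelial, 0.705 and 0.607 for mural, 0.312 and 0.0971 for sex-linked, 0.353 and 0.261 for oligodendrocyte progenitor and 0.636 and 0.288 for erythroid genes. The endothelial median and mean differed in sign, at 0.02 and -0.02 in both fits, with camera lower without and higher with the block. The sex-linked list joins Xist and Tsix with Y chromosome genes, so opposite shifts would offset each other in camera. Xist was lower and Ddx3y higher in the null than in the wild type library of each replicate number. Sex composition thus appears to differ between the genotypes, with more male RNA in the null libraries, although the list did not pass. Neither fit adjusted for sex, so its part in the other calls was not tested.

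**Figure D4:**
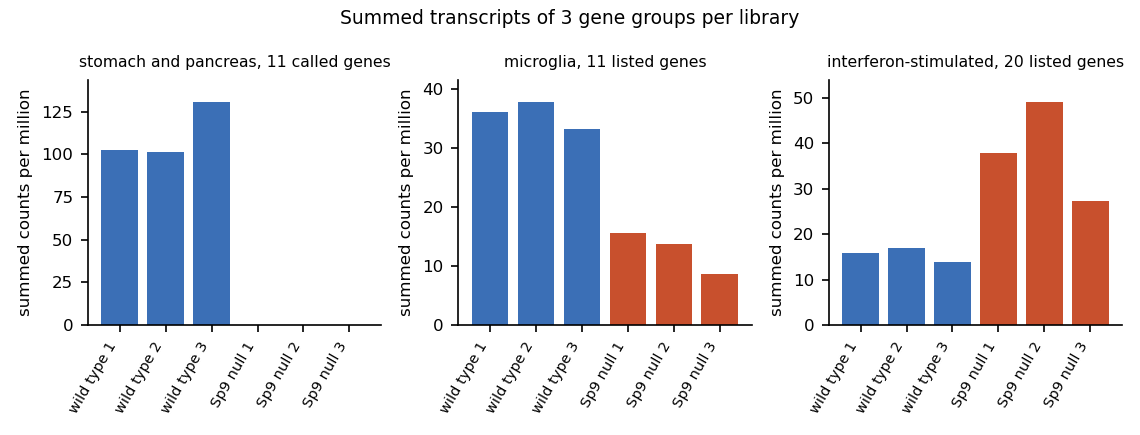
Summed CPM in each of the 6 libraries for the 11 called stomach and pancreas genes, the 11 listed microglial genes and 20 interferon-stimulated genes chosen after seeing the data; bars start at 0. The microglial sum was 35.7 ± 2.33 CPM in wild type and 12.6 ± 3.53 CPM in null libraries (SD, n = 3 each).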

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

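The settings with the block beyond the plain block, those leaving out replicate 2 of both genotypes, genes near Sp9, the gene cluster or genes at 0 in the null libraries were chosen after seeing the data. The fall of Sp9 kept its direction and its call in all settings, from -4.21 to -4.01 with a library left out. The count of 22 called genes became 597 with the replicate block, 65 without a count filter, 84 with DESeq2 and 39 at an adjusted p under 0.1. It ranged from 2 to 34 with a library left out (2, 11 and 6 without wild type replicate 1, 2 and 3, and 34 without null replicate 2), and was 89 without replicate 2 of both genotypes and 10 without genes at 0 in the null libraries. It stayed between 19 and 31 with limma on FPKM, the other scalings, the stricter filter, the fold of 1.5 or without genes within 20 Mb of Sp9. With the block the count was 163 by DESeq2, 614 by limma-voom, 825 without a filter, 561 without genes within 20 Mb of Sp9, 577 without genes at 0 in the null libraries, and 1193, 126 and 219 without pair 1, 2 and 3. The cause was not tested, beyond the fewer libraries or genes that a setting leaves. Of 24 lists, 4 passed, against 5 with the replicate block, 3 to 10 with a library left out and 5 to 7 with the block and a pair left out. The 10 lists without null replicate 2 held only 1 of the 4, microglia, and the pallidal, pan-subpallial and GABA lists did not pass there (adjusted p = 0.377, 0.0546 and 0.224). It was 1 (microglia) with limma on FPKM, 1 with the block and limma-voom, 10 with the block and no filter, and 0 with an estimated correlation or by fry, with or without the block. Unadjusted, 2 lists passed with an estimated correlation and 3 by fry, and 0 and 5 with the block. The cause of reversed values was not tested. Dlx5 was -0.0039 with the block without pair 3. Sst was between -0.516 and 0.337 with a library left out, namely 0.337 without wild type replicate 3 and 0.326 without null replicate 2. Cxcr4 was between -0.140 and 0.0578 with a library left out, namely 0.0368 without wild type replicate 2 and 0.0578 without null replicate 3. With the block it was -0.1455 without pair 1 and 0.0570 without pair 3. Erbb4 was between -0.113 and 0.109, namely 0.109 without wild type replicate 1, 0.0855 without null replicate 2 and 0.0718 with the block without pair 1. Tbr1 was -0.0766 without null replicate 3. All 22 called genes were also called with the block. Depth limits the low genes: 3 counts are 0.273 to 0.440 CPM. The other scalings shifted the median log2 fold change by 0.0083 and 0.0022.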

Other observations

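The edgeR fits of single genes, with and without the block, and the other splits of the libraries were planned. All other tests in this part were chosen after the values they measure, or most of them, were seen. Some interferon-stimulated genes, which are induced in antiviral responses, were higher in the null libraries. Of 11 measured genes of a list drawn up after some of its members had been called, 7 rose and 0 fell with the block. Irgm1, Uba7, Oasl2, Rsad2 and Ddx58 rose by 2.78, 2.40, 2.20, 1.55 and 1.20. Of the 11, 4 did not pass, among them Irf7, at 0.24 (SE 0.40). The 20 listed genes summed to 15.6 ± 1.55 CPM in wild type and 38.0 ± 10.9 CPM in null libraries (SD, n = 3 each). The list includes genes whose rise prompted it, and its camera p was 0.052 with an estimated correlation, so whether the class rose stays open. Of the 5 genes, none kept its blocked call without each of the pairs; Irgm1, Uba7 and Oasl2 lost theirs without pair 2 alone.

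The stomach and pancreas transcripts were counted in all 3 wild type libraries and were at 0 in the null libraries. Of 34 further stomach and pancreas genes looked up before their counts were seen, 21 had 3 or more wild type counts and under 0.1 of them, scaled for depth, in the null libraries (27 of 34 in a list changed after counts were seen), which is consistent with RNA of these organs in the wild type libraries. The 12 called genes at 0 kept the same ratios to each other in the 3 libraries within counting error (chi-square p = 0.479), and a single source shared by them is a candidate explanation. Their summed share differed only 1.28-fold between the highest and the lowest wild type library. A call favours genes that vary little among the wild type libraries, and the 12 include overlapping and near-identical genes. The ratios and the share were thus partly fixed by the selection and do not establish a single source. The labels give no batch, so a step shared by the wild type libraries cannot be told apart from genotype.

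Genes near Sp9 were called more often than others with the block, with an odds ratio of 6.04 within 20 Mb. It was 7.62 among rises and 3.22 among falls, but 4 of the 10 falls are predicted genes clustered at a shared site. Without the 6 tested genes of that cluster it was 5.44, with 7.91 among rises and 1.96 among falls (95% interval 0.70 to 4.40, Fisher's exact test p = 0.138). An effect limited to neighbours within 2 Mb is argued against by the odds ratio of 5.37 between 2 and 20 Mb (Fisher's exact test p = 2.73e-11; 4.67 without the cluster). The odds ratio within 20 Mb, with a lower limit of 4.03, restates the gathering that prompted its test, so it decides neither for a strain haplotype nor against a response of these genes to the loss of Sp9, and both stay open. A strain haplotype carried along with the null allele on the mixed background may contribute, and the calls of all genes within 20 Mb are open to it. Among them are Dlx1, Dlx2, Gad1, Metap1d, Tbr1, Rprm, Pdk1, Itga4 and Ube2l6. Without the cluster 6 falls were left, too few to show or to exclude a gathering of falls, so they do not weigh against a haplotype. The odds ratio was 2.08 between 20 and 40 Mb (95% interval 0.97 to 3.98, Fisher's exact test p = 0.0359) and 0.78 beyond 40 Mb on the chromosome. Lhx6 lies between 20 and 40 Mb from Sp9, so a linked haplotype is not excluded for its call either. No variants were analysed here, so the haplotype itself was not observed.

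Microglial genes were lower in the null libraries. Of 12 further microglial genes looked up before their counts were seen, 11 had a lower pooled CPM in the null libraries. Of the 5 measured, 2 fell, among them Ctss, 1 rose, namely Sall1, which was at 85.6 CPM in wild type libraries, and 2 did not pass with the block (camera p = 0.0679, and 0.204 with an estimated correlation). A list shortened to 9 genes after counts were seen, without Sall1 among others, gave 2.42e-05 and 0.0503, and is not relied on. Whether the fall extends beyond the fixed list, or is owed to the choice of its genes, stays open. Macrophages brought with stomach and pancreas RNA are argued against as the whole cause by the low level of other immune transcripts. The 11 macrophage, antigen presentation and other immune genes pooled to 3.52 CPM in wild type libraries. Their mean fell from 3.5 to 2.53 CPM, by 0.97 CPM (SE 0.38). The mean of the microglial list fell from 35.7 to 12.63 CPM, by 23.07 CPM (SE 2.44). The immune genes could not fall by more than their wild type level, so the argument rests on that level and not on the sizes of the falls. The criterion used, a lower level and a smaller fall of the immune genes, replaced an earlier one. That one, also set after counts were seen, turned on the median of the further microglial genes (-0.458, against a limit of -0.5), which does not measure macrophages. The 9 log2 fold changes differed from each other by more than their approximate errors (chi-square heterogeneity over genes, p = 1.05e-06). That test treats genes of the same libraries as independent and assumes that no other cells contribute counts of these genes. It therefore does not decide whether a lower share of microglia scaled all genes by the same factor. A lower share, with or without changes within the cells, stays open, as does a difference in dissection.

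In the unblocked fit, the real split called 22 genes and the highest of the other 9 splits of the 6 libraries called 2; 1 of 10 splits reached the real count, and 10 splits are too few for a share under 0.05. With the block, the real split called 597 and the highest of the other 3 splits that part all pairs called 0; 1 of 4 splits reached the real count, and these are also too few.

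Cwc22, a splicing factor gene on chromosome 2 (77881159 to 77946375), 4.64 Mb from Sp9, had 9729, 11942 and 10522 counts in wild type replicates 1, 2 and 3 and 433, 2989 and 648 in the null replicates. It passed in neither fit (blocked log2 fold change -3.24, SE 0.70, adjusted p = 0.25). Gm13698 of the cluster near Sp9 had 326, 436 and 334 counts in wild type and 0, 77 and 1 in null replicates, also with null replicate 2 the highest of the null libraries; whether reads are shared between the cluster and Cwc22 was not tested. Of 125 genes of the KEGG ribosome pathway, 20 fell with the block (camera adjusted p = 4.29e-13 at the preset correlation, but 0.974 with an estimated one). Il1f9, an interleukin family gene on chromosome 2, had a blocked log2 fold change of -3.16 (SE 0.51), and Mcc one of 1.31 (SE 0.30); Il1f9 lost its call by DESeq2, and Mcc without pair 2, without pair 3 and by DESeq2. Of 15 liver and intestine genes listed after seeing the data, the summed level was 1.98 CPM in wild type and 2.24 CPM in null libraries.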
